A study of Homo sapiens with 40 samples.

How the data were processed

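Gene expression was measured by 3' RNA sequencing (QuantSeq) in the uveal melanoma cell lines 92.1 and OMM1. Per the labels' protocols, the cells grew in DMEM F12 and RPMI medium with 10 percent FBS in 96-well plates, were transfected with lipofectamine and were lysed after 24 h for library preparation. Each line has 5 treatment groups of 4 replicates, 40 libraries in all: a non-targeting antisense oligonucleotide (NTC ASO, 50 nM), DMSO (0.006 percent), GDC-0349 (0.625 µM), a SAMMSON ASO (50 nM), and GDC-0349 with the SAMMSON ASO. The series text speaks of NTC or SAMMSON ASO combined with DMSO or GDC-0349, but the labels do not say whether the wells with only DMSO or only GDC-0349 also received the NTC ASO, nor whether replicates are separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

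The deposited files hold raw counts per gene from the authors, for 60675 Ensembl identifiers in each library. Per the submitters' processing notes, FastQC 0.11.3, Bowtie2 2.2.3, TopHat and HTSeq 0.6.1 were used with the hg38 genome. The version of TopHat, the annotation release, the strand setting of the counting and any removal of duplicate reads are not given in the sources used here. Counts of overlapping genes are thus uncertain. Of the identifiers, 41706 received a gene symbol, from a table of gene names and from GENCODE 29, and 18969 stayed under their identifier. All columns of the files were used.

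Totals ran from 382730 to 5858673 counts per library, with a median of 1545316. In simulated data with the depth and spread of each group, 200 changed genes and 3 runs, edgeR recovered 2.67 percent of genes changed 2-fold and 31.7 percent of those changed 4-fold for SAMMSON ASO against NTC ASO in 92.1. In OMM1 those values were 23.7 and 78.3 percent. The same simulation for GDC-0349 against DMSO gave 4.33 and 35.3 percent in 92.1, and 30.3 and 82.7 percent in OMM1. With only the 2 groups fitted it gave 33.3 and 68.7 percent in 92.1, where that edgeR fit of the real data also called 0 genes (664 at an unadjusted p under 0.05; DESeq2 called 21 and library weights 60).

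Genes were tested with edgeR 4.0.16 (quasi-likelihood F tests, R 4.3.3) after scaling by TMM. The low-count filter of edgeR (minimum count 10, minimum total count 15) kept 10936 genes in 92.1, 13200 in OMM1 and 14048 in the model of both lines. Each line was fitted with its 20 libraries and 5 groups, and differences between the lines were tested in a model of all 40 libraries. The biological coefficient of variation was 0.659, 0.505 and 0.639 in the 3 fits. The comparisons were SAMMSON ASO with NTC ASO, GDC-0349 with DMSO, the combination with NTC ASO, with SAMMSON ASO and with GDC-0349, and NTC ASO with DMSO. Further contrasts were the interaction (combination minus SAMMSON ASO minus GDC-0349 plus DMSO), the differences between lines, and OMM1 with 92.1 under DMSO. A gene was called at a Benjamini-Hochberg adjusted p under 0.05.

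The comparisons, the alternatives, the gene lists and the rule for the genes named were set before the data were examined. The rule takes, for each line's comparisons of SAMMSON ASO and of the combination with NTC ASO and of GDC-0349 with DMSO, the 5 largest called rises and falls with a mean of at least 10 CPM and no overlap between the groups. For the remaining treatment comparisons it takes the 3 largest in each direction. It adds up to 4 called members of each list by smallest p, and 10 genes called in the same direction in both lines. A few genes it takes are not reported here. Log2 fold changes are given with the standard error of edgeR's fit, and levels as mean ± SD of CPM over 4 libraries. CPM are scaled by the total of the genes kept and the TMM factor, except that floors use that total alone, and ratios and the sums of markers and rRNAs the total of the library. Where a group had no counts, the fold is a lower bound computed against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio of pooled CPM is given with an exact 95 percent interval, and these intervals and floors cover counting error only.

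Of 32 fixed lists, 27 had at least 5 measured members and were tested with camera of limma 3.58.1, with the preset correlation of 0.01 between genes, and again with the correlation estimated from the data. The lists cover ribosomal proteins, ribosome biogenesis, mitochondrial genes, stress responses, p53 targets, the cell cycle, lipid synthesis, pigmentation and other programmes. List p-values are camera's, adjusted over the lists of a comparison. Counts of list members called are given at the adjustment over all genes and, as "over the list alone", after adjusting only over the members. Markers of endothelial, epithelial, fibroblast and leukocyte cells and the 2 mitochondrially encoded rRNAs were too few after the filter for a test.

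The alternatives were RLE scaling, no low-count filter, DESeq2 1.42.0, a replicate block, a fit of only the groups compared, and each library left out in turn. Added after seeing the data were limma voom with library weights, counts thinned to the smallest total of 382730, fits without the combination libraries, and fits without the 12 genes among the 10 most counted of either line. The thinning, without replacement, was changed after seeing results: a first version drew with replacement, which adds noise, and called fewer genes for the SAMMSON ASO in 92.1. Group labels were also split in all 35 balanced ways for 2 groups, and in 100 or 60 drawn at random for the interactions and line differences, to learn how many calls arise among mixed groups. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.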

Results

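The 40 libraries cover both lines under 5 treatments for 24 h, 4 replicates each. GDC-0349 with the SAMMSON ASO is called the combination below. GDC-0349 is an inhibitor of the kinase mTOR, and SAMMSON is a long non-coding RNA of melanoma whose gene lies 31212 bases downstream of MITF on chromosome 3.

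Genes detected per library, counted at an equal depth of 382730 counts, were fewest in the combination libraries of 92.1. They held 9391 to 10221 genes, against 11104 to 13211 in the other 92.1 libraries. The combination libraries of OMM1 held 12339 to 13019 genes. The spread between replicates was widest there too: the biological coefficient of variation was 1.16 in the 92.1 combination group and 0.386 to 0.605 in the other 92.1 groups. In OMM1 it was 0.673 for the combination and 0.371 to 0.499 elsewhere. The OMM1 combination libraries were also the deepest, with 3499039 to 5858673 counts.

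**Figure D1:**
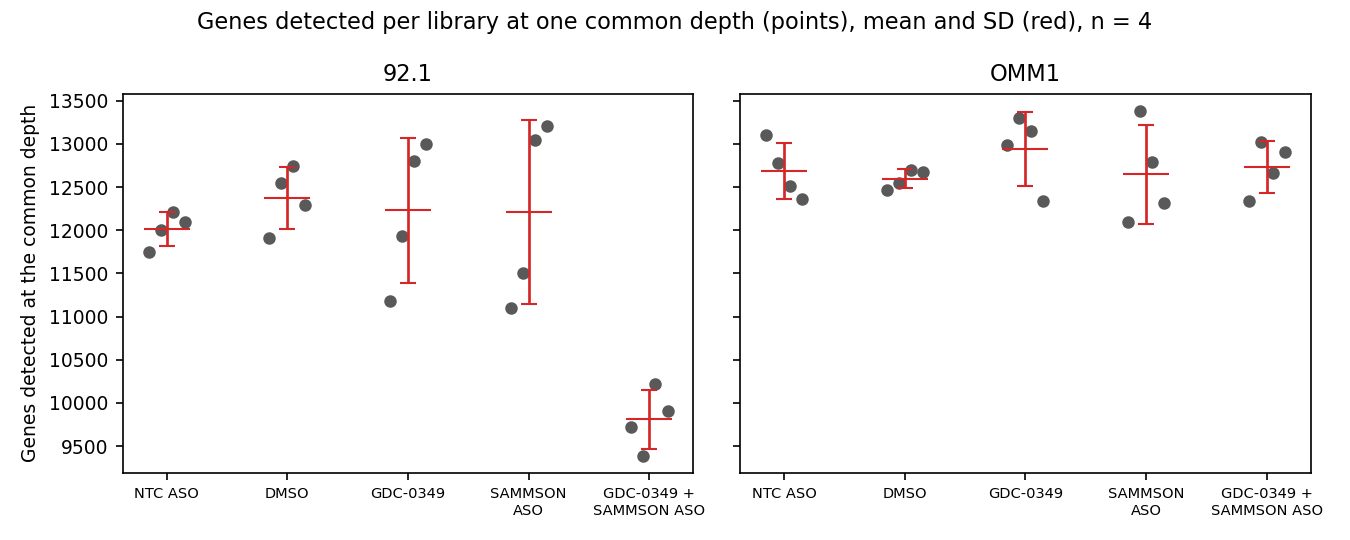
Number of genes detected in each library after thinning to 382730 counts, by treatment group and line (points). The 92.1 combination libraries hold 9391 to 10221 genes, the fewest of all groups.

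SAMMSON itself was counted at low levels. In OMM1 it stood at 14.1 ± 4.27 CPM with NTC ASO and 8.11 ± 4.59 CPM with the SAMMSON ASO (mean ± SD, n = 4 and 4). It stood at 16.5 ± 10.3 CPM with DMSO, 21.3 ± 11.2 with GDC-0349 and 5.32 ± 1.96 with the combination. In 92.1 it was at 7.25 ± 7.82 CPM with NTC ASO, 2.19 ± 2.83 with the SAMMSON ASO, 13.6 ± 19.7 with DMSO, 3.85 ± 2.62 with GDC-0349 and 3.74 ± 5.87 with the combination. Single libraries carry the 92.1 means: NTC ASO replicate 2 held 16.8 CPM, SAMMSON ASO replicate 4 6.34, DMSO replicate 1 43 and combination replicate 4 12.5. In no line did SAMMSON ASO against NTC ASO pass the test for SAMMSON: the log2 fold change was -1.65 ± 1.51 in 92.1 (adjusted p = 0.919) and -0.83 ± 0.64 in OMM1 (adjusted p = 0.607). The combination against NTC ASO did not pass either, at -0.89 ± 1.48 (adjusted p = 0.81) and -1.41 ± 0.62 (adjusted p = 0.13). SAMMSON fell in OMM1 with the combination against GDC-0349 (-1.99 ± 0.62, 3.98-fold lower, adjusted p = 0.0219). That call ended without GDC-0349 replicates 1 and 3 and combination replicates 1 and 4, with an adjusted p of up to 0.127. With 0 to 18 counts per library in 92.1, the knockdown cannot be measured.

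**Figure D2:**
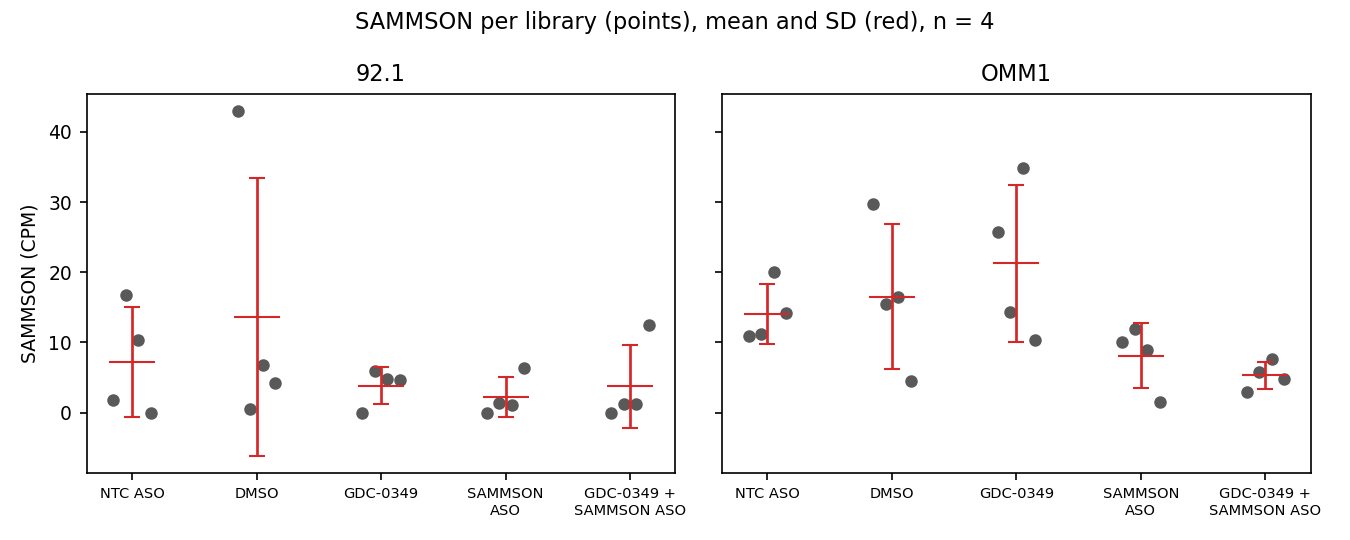
SAMMSON level in CPM in each library (points) with the mean and SD of each group, by line. OMM1 means are 14.1 CPM with NTC ASO, 8.11 with the SAMMSON ASO and 5.32 with the combination.

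MITF, the melanocyte lineage regulator next to SAMMSON, was not called under the SAMMSON ASO. In 92.1 it was at 194 ± 63.1 CPM with NTC ASO and 229 ± 14.3 CPM with the SAMMSON ASO (0.23 ± 0.24, adjusted p = 0.94). In OMM1 it was at 323 ± 63.4 and 265 ± 21.5 CPM (-0.28 ± 0.16, adjusted p = 0.421). MITF was at 250 ± 36.9, 255 ± 64.8 and 163 ± 31.8 CPM with DMSO, GDC-0349 and the combination in 92.1, and at 341 ± 30.5, 355 ± 35.8 and 260 ± 49.4 CPM in OMM1. It was called once, lower in OMM1 with the combination than with GDC-0349 (-0.45 ± 0.16, 1.36-fold, adjusted p = 0.0466). That call ended in every fit without 1 of the 8 libraries, except that without combination replicate 4 (adjusted p up to 0.179), and also without the low-count filter and with thinned counts. Among the 25 and 28 measured genes of the melanocyte lineage and pigmentation list, 0 were called under the SAMMSON ASO in either line by edgeR (median log2 fold change -0.099, adjusted p = 0.22 in 92.1 and -0.076, adjusted p = 0.566 in OMM1). Over the list alone, 1 fell in 92.1 and 0 in OMM1.

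With the SAMMSON ASO, 92.1 cells held more RNA of PMAIP1, a pro-apoptotic BH3-only gene of the BCL2 family, and of GADD45A, a p53-responsive growth arrest gene (n = 4 and 4 libraries). PMAIP1 rose from 37.1 ± 10.3 CPM with NTC ASO to 168 ± 14.7 CPM (log2 fold change 2.19 ± 0.44, 4.56-fold, adjusted p = 0.00463). GADD45A rose from 50.3 ± 21.5 to 207 ± 33.6 CPM (2.08 ± 0.38, 4.22-fold, adjusted p = 0.00191). SNHG25 and SNHG1, host genes of small nucleolar RNAs, rose 4.71-fold (2.24 ± 0.23, adjusted p = 5.36e-08) and 2.81-fold (1.49 ± 0.21, adjusted p = 3.3e-05). FGF18, a fibroblast growth factor gene, had 1 count over the NTC ASO libraries and 539 with the SAMMSON ASO, a ratio of 313 (55.9 to 12400, adjusted p = 3.01e-06).

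The largest rises in 92.1 further held NACAD, at least 49.4-fold higher (adjusted p = 0.000371), GARIN4, at least 23.3-fold, MMP25, at least 25.4-fold, and MAP7D2, at least 20.7-fold. The last 3 calls ended without single NTC ASO libraries: replicates 1 and 2 for GARIN4 (adjusted p up to 0.0778) and MAP7D2 (up to 0.0878), and each of the 4 for MMP25 (up to 0.0946). The largest falls were RPS6KB2, a ribosomal S6 kinase gene (-2.79 ± 0.61, 6.89-fold, adjusted p = 0.0118), MRPL12, a protein of the mitochondrial ribosome (-2.68 ± 0.67, 6.41-fold, adjusted p = 0.0375) and PET117, a cytochrome c oxidase assembly factor (-2.12 ± 0.52, 4.36-fold, adjusted p = 0.034). MPST (-2.08 ± 0.45, 4.24-fold, adjusted p = 0.0118) and NPLOC4 (-2.0 ± 0.50, 4.01-fold, adjusted p = 0.0356) also fell. Each of these 5 calls ended in some fits without 1 library. RPS6KB2 lost its call without SAMMSON ASO replicate 1, 2 or 3 (adjusted p up to 0.0796), and without replicate 4 its fall was -3.70. MPST lost it without SAMMSON ASO replicate 1 or 3 (up to 0.0812) and MRPL12 without any library but SAMMSON ASO replicate 3 (up to 0.137). PET117 lost it without NTC ASO replicates 1 to 3 or SAMMSON ASO replicates 1 to 3 (up to 0.205), and NPLOC4 without NTC ASO replicates 1 to 3 or SAMMSON ASO replicates 1, 2 and 4 (up to 0.158).

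By group in 92.1, cytosolic ribosomal protein genes moved up together: 10 of 83 measured members rose and 0 fell, 26 and 1 over the list alone (median 0.28, adjusted p = 2.59e-12, but 0.251 with estimated correlation). RPL7 (0.89 ± 0.12, 1.85-fold), RPL27A (0.79 ± 0.11, 1.73-fold) and RPS10 (0.66 ± 0.12, 1.58-fold) are examples. Among ATF4 targets of the integrated stress response, 3 of 29 rose and 0 fell, 4 and 0 over the list alone (median 0.46, adjusted p = 0.00347, but 0.0698 with estimated correlation). ASNS, the asparagine synthetase, rose 3.13-fold (1.65 ± 0.34, adjusted p = 0.0064) without loss of the call in any fit. ATF4 itself (0.81 ± 0.19, adjusted p = 0.0189) and PPP1R15A (1.47 ± 0.32, adjusted p = 0.0129) rose as well. The ATF4 call ended without NTC ASO replicate 1 or 3 or SAMMSON ASO replicate 1 or 3 (adjusted p up to 0.0997), and that of PPP1R15A without NTC ASO replicate 1 or 3 or SAMMSON ASO replicate 3 (up to 0.0871). Ribosome biogenesis genes shifted up (2 of 37 rose, 6 over the list alone, 0 fell, median 0.22, adjusted p = 0.0338, but 0.251 with estimated correlation). NOP56 stood at 0.80 ± 0.15 (1.74-fold, adjusted p = 0.00236). Fatty acid synthesis genes shifted down with 0 of 12 called (1 fell over the list alone, median -0.40, adjusted p = 0.0122, but 0.0698 with estimated correlation).

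In total edgeR called 88 of 10936 genes in 92.1 under the SAMMSON ASO, 71 higher and 17 lower. The count was 41 without NTC ASO replicate 1, 51 without NTC ASO replicate 2, 52 without SAMMSON ASO replicate 3 and 58 without SAMMSON ASO replicate 4. It was 238 when only the NTC ASO and SAMMSON ASO libraries were fitted, 240 with DESeq2, 345 with library weights and 300 without the combination libraries.

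In OMM1 the SAMMSON ASO went with higher PMAIP1 and GADD45A as well (n = 4 and 4). PMAIP1 rose from 4.49 ± 2.14 to 38.1 ± 9.97 CPM (3.16 ± 0.50, 8.95-fold, adjusted p = 4.9e-05), and GADD45A from 72.9 ± 18.4 to 394 ± 62.3 CPM (2.46 ± 0.20, 5.49-fold, adjusted p = 1.85e-12). FGF18 rose from 4.54 ± 4.68 to 73.0 ± 24.4 CPM (4.49 ± 0.56, 22.4-fold, adjusted p = 3.27e-07). It stood at 5.11 without NTC ASO replicate 1 and at 3.84 without replicate 3. The other largest rises were ZFAND2A-DT (3.89 ± 0.82, 14.8-fold, adjusted p = 0.0022), PAPOLA-DT (3.80 ± 1.1, 13.9-fold, adjusted p = 0.0362), MED18 (3.69 ± 0.68, 12.9-fold, adjusted p = 0.00049) and TXNIP, a thioredoxin-binding regulator of glucose uptake (3.62 ± 0.65, 12.3-fold, adjusted p = 0.000368). Without NTC ASO replicate 1, ZFAND2A-DT stood at 5.93, PAPOLA-DT at 5.44 and MED18 at 4.50. Without NTC ASO replicate 3, ZFAND2A-DT stood at 3.27 and PAPOLA-DT at 3.21. The PAPOLA-DT call ended without any library but NTC ASO replicate 1 (adjusted p up to 0.138) and without the combination libraries.

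The largest falls in OMM1 were TRIM71 (-2.24 ± 0.55, 4.72-fold, adjusted p = 0.0105), CLDN12 (-2.21 ± 0.64, 4.63-fold, adjusted p = 0.0352), CHTF18 (-2.16 ± 0.62, 4.47-fold, adjusted p = 0.0352), CCDC88C (-2.15 ± 0.57, 4.43-fold, adjusted p = 0.0199) and TAF1C (-2.11 ± 0.47, 4.32-fold, adjusted p = 0.00392). CLDN12 lost its call without any library but SAMMSON ASO replicate 2 (adjusted p up to 0.117). CHTF18 lost it without NTC ASO replicate 2 or 4 or SAMMSON ASO replicate 1, 3 or 4 (up to 0.218), and CCDC88C without NTC ASO replicate 1 or 4 or SAMMSON ASO replicates 2 to 4 (up to 0.0671). CLDN12 and CHTF18 also lost it with library weights, CLDN12 without the low-count filter and CHTF18 with thinned counts. MRPL12 fell in OMM1 too (-1.89 ± 0.41, 3.7-fold, adjusted p = 0.00384).

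By group in OMM1, 8 of 29 p53 targets rose and 1 fell, the same over the list alone (median 0.43, adjusted p = 2.11e-07; 0.000324 with estimated correlation). Besides GADD45A these held CDKN1A, the cell cycle inhibitor p21 (1.40 ± 0.21, 2.64-fold, adjusted p = 2.43e-05), TRIAP1 (1.40 ± 0.15, 2.64-fold, adjusted p = 1.01e-08) and PHLDA3 (1.26 ± 0.22, 2.39-fold, adjusted p = 0.000235). Cytosolic ribosomal protein genes rose (48 of 83, 69 over the list alone, 0 and 1 fell, median 0.55, adjusted p = 1.87e-36; 0.0206 with estimated correlation). RPS14 stood at 0.97 ± 0.13 (1.96-fold) and RPL27A at 0.80 ± 0.12 (1.74-fold). Of 15 genes of the cytosolic heat shock response, 6 rose and 0 fell, 9 and 0 over the list alone (median 0.46, adjusted p = 6.43e-05; 0.0188 with estimated correlation). HSP90AA1 (0.48 ± 0.09, 1.39-fold) and HSPA8 (0.66 ± 0.14, 1.58-fold) are examples. MYC targets moved up with 3 of 30 called (6 over the list alone, median 0.36, adjusted p = 0.00202; 0.0225 with estimated correlation). NME1 is among them (0.77 ± 0.17, 1.71-fold).

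Mitochondrial groups moved up in OMM1 by camera with the preset correlation. Of 13 mitochondrially encoded mRNAs 4 rose (median 0.26, adjusted p = 0.00202, but 0.132 with estimated correlation). MT-ND3 is an example (0.50 ± 0.10, 1.42-fold, adjusted p = 0.00138). Of 52 nuclear subunits of oxidative phosphorylation 2 rose, 3 over the list alone (median 0.34, adjusted p = 0.000396, but 0.241 with estimated correlation). Of 76 mitochondrial ribosomal proteins 6 rose and 3 fell, 6 and 4 over the list alone (median 0.22, adjusted p = 0.021, but 0.125 with estimated correlation). MRPL33 (0.75 ± 0.14, 1.68-fold, adjusted p = 0.000748) rose and MRPL12 fell. ATF4 targets moved up (5 of 30 rose, 10 over the list alone, 0 fell, median 0.54, adjusted p = 0.00112, but 0.0987 with estimated correlation). GDF15, a stress-induced cytokine, stood at 1.15 ± 0.12 (2.23-fold, adjusted p = 4.07e-09).

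In total edgeR called 515 of 13200 genes in OMM1 under the SAMMSON ASO, 342 higher and 173 lower. The count was 324 without NTC ASO replicate 3, 335 without NTC ASO replicate 4 and 312 without SAMMSON ASO replicate 3.

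Lists with no call by camera in either line under the SAMMSON ASO follow, as members called higher and lower of those measured in 92.1 and then OMM1. They are autophagy (0 and 0 of 28, 1 and 1 of 29), interferon response (0 and 0 of 14, 1 and 0 of 20), lysosome (0 and 0 of 37, 2 and 1 of 39) and mitochondrial chaperones and proteases (0 and 0 of 15, 1 and 0 of 15). Mitochondrial RNA processing had 0 and 1 of 30 in 92.1, 2 and 2 of 32 in OMM1. NF-kB targets had 0 and 0 of 7, 1 and 0 of 10, and YAP targets 0 and 0 of 15, 3 and 1 of 17. Glycolysis and HIF1 targets had 1 and 0 of 24, 2 and 0 of 28, MAPK output 1 and 0 of 17, 3 and 0 of 18, and cholesterol synthesis 0 and 0 of 23, 0 and 1 of 24. FOXO targets had 0 and 0 of 26, 2 and 0 of 25, tRNA synthetases 0 and 0 of 20, 1 and 0 of 20, and BCL2 family genes 1 and 0 of 12, 2 and 0 of 14. Endoplasmic reticulum stress genes had 0 and 0 of 21, 0 and 0 of 23, genes of G2 and mitosis 0 and 0 of 29, 2 and 1 of 29, and S phase genes 1 and 0 of 29, 0 and 0 of 29. The camera adjusted p of these lists ran from 0.165 to 0.875 in 92.1 and from 0.0678 to 0.802 in OMM1.

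Several lists passed in 1 line and not in the other. In 92.1 the p53 targets (1 rose and 1 fell of 28, adjusted p = 0.103), heat shock genes (1 and 0 of 14, adjusted p = 0.103), MYC targets (0 and 0 of 30, adjusted p = 0.0848), nuclear OXPHOS subunits (0 and 0 of 51, adjusted p = 0.509), mitochondrial ribosomal proteins (1 and 1 of 74, adjusted p = 0.71) and mitochondrially encoded mRNAs (0 and 0 of 13, adjusted p = 0.103) did not pass. In OMM1 ribosome biogenesis (3 and 0 of 37, adjusted p = 0.0555) and fatty acid synthesis (0 and 0 of 15, adjusted p = 0.131) did not pass. Of these lists, the test of the difference between lines passed for mitochondrially encoded mRNAs, higher in OMM1 (median 0.44, 0 of 13 called, 5 over the list alone, adjusted p = 1.79e-06, but 0.273 with estimated correlation). It also passed for nuclear OXPHOS subunits (median 0.35, adjusted p = 8.03e-05, but 0.501 with estimated correlation) and, of the lists called in both lines, for ribosomal proteins (median 0.22, adjusted p = 4.13e-06, but 0.663 with estimated correlation).

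The same genes recurred in both lines under the SAMMSON ASO. Of 10462 genes tested in both, 46 were called higher in each line, against 2.13 expected (exact hypergeometric p = 1.28e-53), and 8 lower, against 0.27 expected (p = 7.31e-11). Of the 87 genes called in 92.1, 86 had the same sign in OMM1. Genes called in both with the largest smaller fold include FGF18, PMAIP1, GADD45A, SNHG25 and SNHG1 among the rises, with HEXIM1, an inhibitor of the elongation factor P-TEFb. SNHG25 rose by 2.06 ± 0.17 in OMM1 (4.16-fold) and SNHG1 by 1.47 ± 0.17 in OMM1 (2.78-fold). HEXIM1 rose by 2.53 ± 0.52 in 92.1 (5.76-fold, adjusted p = 0.00686) and 1.77 ± 0.18 in OMM1 (3.41-fold). Its call in 92.1 ended without NTC ASO replicate 1 (adjusted p = 0.0572), and it stood at 3.15 without NTC ASO replicate 4. The falls are MRPL12, PET117 (-1.57 ± 0.36 in OMM1, 2.98-fold, adjusted p = 0.00548) and RPS6KB2 (-1.54 ± 0.39 in OMM1, 2.92-fold, adjusted p = 0.0136). The RPS6KB2 call in OMM1 ended without NTC ASO replicate 4 or SAMMSON ASO replicate 3 (up to 0.0876).

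No gene's response to the SAMMSON ASO was called different between the lines by edgeR (0 of 14048, 745 at an unadjusted p under 0.05). The count was 5 without the low-count filter, 12 with DESeq2 and 0 with library weights. SNHG1 and SNHG25 overlap their small nucleolar RNAs, PET117 overlaps KAT14, and HEXIM1, RPS6KB2, MPST and NPLOC4 overlap genes on the opposite strand. Their counts are uncertain, since the strand setting is not given.

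**Figure D3:**
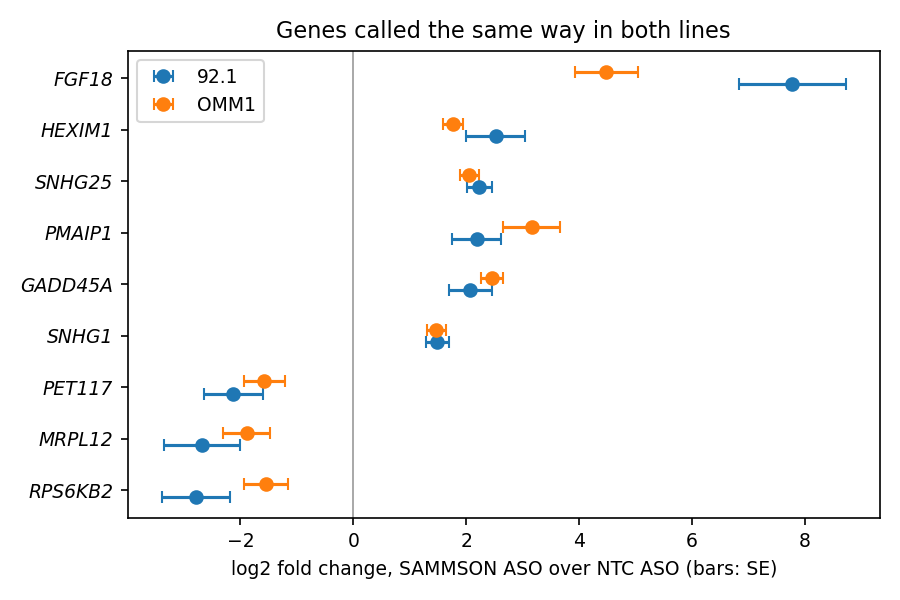
Log2 fold change ± standard error with the SAMMSON ASO against NTC ASO for 9 genes called in both lines (n = 4 and 4 libraries per line). The 6 rises and 3 falls share their direction, with PMAIP1 at 2.19 and 3.16, and the fitted value of FGF18 in 92.1 rests on 1 count in the controls.

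Few single genes were called under GDC-0349 alone, at 0.625 µM and 24 h (n = 4 and 4 in each line). In OMM1, 5 of 13200 genes were called. BCYRN1, a small brain cytoplasmic RNA gene with many near-identical copies, fell from 87600 ± 6540 to 48300 ± 6940 CPM (-0.86 ± 0.09, 1.81-fold, adjusted p = 2.58e-09). SNHG9 fell (-1.30 ± 0.22, 2.46-fold, adjusted p = 0.00177), and ATF3, a stress-induced transcription factor, rose from 1.25 ± 1.45 to 13.0 ± 4.42 CPM (3.33 ± 0.66, 10.1-fold, adjusted p = 0.0335). DPYSL2 rose (0.94 ± 0.20, 1.93-fold, adjusted p = 0.0468), and so did RAB11B-AS1 (5.84 ± 1.22, adjusted p = 0.0468), which lies outside the rule for named genes and was chosen after its value was seen.

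Apart from BCYRN1, the named calls of GDC-0349 in OMM1 hung on single libraries. SNHG9 lost its call without GDC-0349 replicate 4 (adjusted p = 0.0548). ATF3 lost it without DMSO replicate 1 or 2 or GDC-0349 replicate 1, 2 or 4 (up to 0.153), and stood at 4.60 without DMSO replicate 3. DPYSL2 lost it without any library but DMSO replicate 4 (up to 0.494). SNHG9, ATF3 and DPYSL2 also lost it with only the 2 groups fitted and with thinned counts. The count of 5 became 2 without DMSO replicate 1, 34 without DMSO replicate 4, and 3, 2, 3 and 1 without GDC-0349 replicates 1 to 4. It was 20 without the low-count filter, 22 with DESeq2, 22 with library weights, 9 with the replicate block, 3 with thinned counts, 2 without the most counted genes, 2 without the combination libraries and 1 with only the 2 groups fitted.

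In 92.1, edgeR called 0 of 10936 genes under GDC-0349, with 283 at an unadjusted p under 0.05. DESeq2 called 21 and library weights 60. The edgeR count was 1 without DMSO replicate 3 and 2 without GDC-0349 replicate 1, and 5 without the low-count filter. As a group, genes of cholesterol synthesis and uptake shifted down in 92.1 although 0 of 23 were called (3 fell over the list alone, median -0.54, adjusted p = 4.71e-09; 0.000832 with estimated correlation). HMGCS1, the cytosolic HMG-CoA synthase, stood at 297 ± 91.3 CPM with GDC-0349 and 525 ± 70.9 CPM with DMSO (-0.82 ± 0.20, adjusted p = 0.34). Endoplasmic reticulum unfolded protein response genes shifted down (0 of 21 called, 6 fell over the list alone, median -0.33, adjusted p = 1.04e-05; 0.0449 with estimated correlation). So did genes of G2 and mitosis (0 of 29, median -0.31, adjusted p = 0.000515; 0.0449 with estimated correlation). S phase genes had a median of -0.38 (0 of 29, adjusted p = 0.000273, but 0.0542 with estimated correlation). Ribosomal protein genes shifted up (0 of 83 called, 8 rose over the list alone, median 0.22, adjusted p = 9.1e-14, but 0.152 with estimated correlation).

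In OMM1 under GDC-0349, ribosomal protein genes shifted up (0 of 83 called, 3 rose over the list alone, median 0.16, adjusted p = 4.21e-07, but 0.262 with estimated correlation). The aminoacyl-tRNA synthetases shifted down (0 of 20, median -0.22, adjusted p = 0.00891; 0.0498 with estimated correlation). Genes of G2 and mitosis shifted up (0 of 29, median 0.15, adjusted p = 0.00891; 0.0498 with estimated correlation). By camera the lines differed in response to GDC-0349 for G2 and mitosis (median difference, OMM1 minus 92.1, 0.51, adjusted p = 2.7e-06; 0.00292 with estimated correlation). They differed also for S phase genes (0.44, adjusted p = 7.33e-05; 0.0252 with estimated correlation), cholesterol synthesis (0.34, adjusted p = 0.00506; 0.0383 with estimated correlation) and the tRNA synthetases (-0.24, adjusted p = 0.041; 0.0498 with estimated correlation). The unfolded protein response (0.4, adjusted p = 0.00149, but 0.0711 with estimated correlation) and mitochondrial chaperones (-0.29, adjusted p = 0.0422, but 0.0509 with estimated correlation) differed only with the preset correlation. These list differences had no label splits. By single genes edgeR called 0 differences (453 at an unadjusted p under 0.05). It called 1 without DMSO replicate 4 of 92.1 and 2 without the low-count filter, DESeq2 1 and library weights 4.

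The combination in 92.1 went with a rise of DDIT3, the stress-induced transcription factor CHOP, from 38.0 ± 20 to 279 ± 66.6 CPM against NTC ASO (2.92 ± 0.45, 7.56-fold, adjusted p = 3.89e-05, n = 4 and 4). PMAIP1 rose (2.16 ± 0.44, 4.48-fold, adjusted p = 0.0013), as did BBC3, another BH3-only gene (1.47 ± 0.36, 2.77-fold, adjusted p = 0.00921). MKI67, the proliferation marker Ki-67, fell (-2.61 ± 0.40, 6.11-fold, adjusted p = 2.71e-05). The largest rises were NACAD, at least 90.5-fold, MAP7D2, at least 47.9-fold, GARIN4, at least 47.5-fold, IL31, at least 30.9-fold, and FGF18, with 821 counts against 1 (ratio 519, 93 to 20500). The largest falls were CNPY3, at least 55.0-fold, TNIK, at least 44.6-fold, KNTC1, at least 37.7-fold, ABCC4, at least 35.6-fold, and SGO1, a protector of centromeric cohesion, with 1 count against 196 (ratio 310, 55 to 12300). With library weights the calls of CNPY3, TNIK, KNTC1 and ABCC4 ended.

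By group, cytosolic ribosomal proteins rose with the combination in 92.1 (49 of 83 rose and 2 fell, 64 and 2 over the list alone, median 0.64, adjusted p = 4.43e-39; 0.0171 with estimated correlation). RPL7 (1.39 ± 0.13, 2.62-fold) and RPS12 (1.11 ± 0.10, 2.16-fold) lead them. Fatty acid synthesis genes fell, 4 of 12 and none the other way, 8 over the list alone (median -1.06, adjusted p = 0.000247; 0.0136 with estimated correlation). FASN, the fatty acid synthase, is an example (-1.35 ± 0.27, 2.54-fold, adjusted p = 0.00117). ATF4 targets moved up (4 of 29 rose and 1 fell, 5 and 1 over the list alone, median 0.69, adjusted p = 0.00189; 0.0454 with estimated correlation). ATF4 (1.26 ± 0.19, 2.4-fold) and ASNS (1.42 ± 0.34, 2.68-fold, adjusted p = 0.00593) rose. S phase genes (5 of 29 fell, the same over the list alone, median -0.74, adjusted p = 0.00172, but 0.0706 with estimated correlation) and genes of G2 and mitosis (3 of 29 fell, 8 over the list alone, median -0.48, adjusted p = 0.00172, but 0.0508 with estimated correlation) moved down. TOP2A stood at -0.83 ± 0.15 (1.78-fold). FOXO targets and growth factor receptors moved up, 4 of 26 in either count (median 0.51, adjusted p = 0.0349, but 0.0508 with estimated correlation). ERBB3 rose 3.58-fold (1.84 ± 0.40, adjusted p = 0.00241).

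In all, 843 of 10936 genes were called, 336 higher and 507 lower, in the group of fewest genes detected and widest spread. Long non-coding RNAs took 8.58 ± 0.425 percent of its counts and MALAT1 5.81 ± 0.461, against 5.87 ± 0.288 and 3.99 ± 0.302 with NTC ASO; with GDC-0349 alone they took 8.14 ± 0.666 and 5.76 ± 0.827. With only the 2 groups fitted the count was 256 (183 higher, 73 lower, 249 of them among the 843), with library weights 223 (184 higher, 39 lower, 216 among the 843), with DESeq2 1380, and without NTC ASO replicate 1 it was 554. In data simulated with each group's own spread, edgeR made 75 false calls among 131.

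With the combination in OMM1, PMAIP1 rose from 4.49 ± 2.14 to 73.9 ± 27.7 CPM (4.11 ± 0.50, 17.2-fold, adjusted p = 7.12e-08, n = 4 and 4) and GADD45A by 2.66 ± 0.20 (6.34-fold, adjusted p = 3.31e-14). FGF18 rose from 4.54 ± 4.68 to 224 ± 35.5 CPM (6.09 ± 0.56, 68-fold, adjusted p = 4.38e-11). It stood at 6.71 without NTC ASO replicate 1 and at 5.44 without replicate 3. TXNIP rose 18.6-fold (4.22 ± 0.65, adjusted p = 5.91e-06), and CAPN3 fell (-2.0 ± 0.26, 4.01-fold, adjusted p = 2.2e-07). The other largest rises were APC2 (360 counts against 1, ratio 117, 20.8 to 4630), H2AC25 (401 against 2, ratio 65.1, 17.9 to 539), ZFAND2A-DT (4.43 ± 0.81, 21.6-fold) and VTRNA1-2 (4.41 ± 1.12, 21.2-fold, adjusted p = 0.00507). ZFAND2A-DT stood at 6.48 without NTC ASO replicate 1 and 3.81 without replicate 3, and VTRNA1-2 at 5.47 without NTC ASO replicate 4. The largest falls were AKAP11 (-3.06 ± 0.60, 8.34-fold, adjusted p = 0.00024), ZNF321P (-2.97 ± 0.94, 7.84-fold, adjusted p = 0.027), PDPK1, the kinase PDK1 upstream of AKT (-2.92 ± 0.62, 7.56-fold, adjusted p = 0.000685), FAM199X (-2.78 ± 0.75, 6.87-fold, adjusted p = 0.00822) and PLIN5 (-2.74 ± 0.69, 6.68-fold, adjusted p = 0.00421). ZNF321P lost its call without NTC ASO replicate 1, 2 or 4 or combination replicate 2 or 4 (adjusted p up to 0.0781), and stood at -3.93 without combination replicate 3. FAM199X lost it without NTC ASO replicate 2 (0.0705) and with library weights, and PDPK1 stood at -3.55 without combination replicate 4.

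By group, p53 targets rose with the combination in OMM1: 12 of 29 rose and 1 fell, 14 and 2 over the list alone (median 0.88, adjusted p = 4.72e-08; 0.000197 with estimated correlation). TRIAP1 (1.41 ± 0.15, 2.65-fold), PHLDA3 (1.58 ± 0.22, 2.99-fold) and CDKN1A (1.29 ± 0.21, 2.45-fold) are among them. Of the ribosomal proteins 63 of 83 rose and 1 fell, 72 and 1 over the list alone (median 0.74, adjusted p = 1.13e-40; 0.0198 with estimated correlation). RPL36AL rose 3.49-fold (1.80 ± 0.21). The remaining calls held only with the preset correlation. They were nuclear OXPHOS subunits (19 of 52 rose and 1 fell, 29 and 2 over the list alone, median 0.50, adjusted p = 6.34e-07, but 0.165 with estimated correlation), such as COX7C (1.20 ± 0.17, 2.29-fold). They were also mitochondrially encoded mRNAs (6 of 13 rose and 1 fell, 8 and 1 over the list alone, median 0.35, adjusted p = 0.00783, but 0.171 with estimated correlation). Heat shock genes rose (9 of 15 rose and 1 fell, 11 and 3 over the list alone, median 0.55, adjusted p = 0.00161, but 0.0558 with estimated correlation). HSPA8 stood at 1.13 ± 0.14 (2.19-fold). ATF4 targets had 11 of 30 higher in either count (median 0.41, adjusted p = 0.00164, but 0.105 with estimated correlation). DDIT3 stood at 1.36 ± 0.26 (2.56-fold, adjusted p = 0.000148).

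Further calls in OMM1 were FOXO targets (5 of 25 rose and 1 fell, 10 and 2 over the list alone, median 0.58, adjusted p = 0.00644, but 0.0589 with estimated correlation). IRS2, an insulin receptor substrate, stood at 1.54 ± 0.24 (2.9-fold). MYC targets moved up (8 of 30 rose, 9 over the list alone, 0 fell, median 0.42, adjusted p = 0.0133, but 0.0589 with estimated correlation). Aminoacyl-tRNA synthetases moved down (1 of 20 rose and 5 fell, 1 and 7 over the list alone, median -0.30, adjusted p = 0.0393, but 0.105 with estimated correlation). RARS1 stood at -0.73 ± 0.14 (1.66-fold). Of the pigmentation genes, 1 of 28 rose and 3 fell (adjusted p = 0.161), and of the YAP targets 7 of 17 rose and 2 fell (adjusted p = 0.061). CCN1 rose by 2.83 ± 0.39 (7.09-fold, adjusted p = 7.89e-07). In all, 1802 of 13200 genes were called with the combination, 974 higher and 828 lower.

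Calls of the combination against NTC ASO met in both lines more often than expected: 184 genes were higher in each line (26.5 expected, exact hypergeometric p = 3.17e-119), 125 lower (35.4 expected, p = 1.89e-38) and 6 opposite, of 10462 tested in both. MT-TL1, a mitochondrial leucine tRNA, rose 4.89-fold in 92.1 (2.29 ± 0.19, adjusted p = 1.54e-10) and 8.75-fold in OMM1 (3.13 ± 0.19, adjusted p = 2.24e-17). SNHG25 rose 4.05-fold (2.02 ± 0.23) and 5.01-fold (2.33 ± 0.17), and GADD45A rose 3.74-fold in 92.1 (1.90 ± 0.38). ELOVL3, a fatty acid elongase, rose 53.4-fold in 92.1 (5.74 ± 0.96, adjusted p = 0.000147) and 19.5-fold in OMM1 (4.28 ± 0.97, adjusted p = 0.00157). In 92.1 it stood at 5.04 without NTC ASO replicate 1 and at 5.13 without combination replicate 4.

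Between the lines, 229 of 14048 responses to the combination were called different, 195 higher in OMM1 and 34 in 92.1. The median difference over all genes was 0.12. MRPS34, of the small mitochondrial ribosomal subunit, fell in 92.1 (-3.38 ± 0.44, 10.4-fold, adjusted p = 1.53e-06), with a difference of 2.81 ± 0.48 (adjusted p = 0.000399). The difference was 3.45 ± 0.69 for NDUFS8, a complex I subunit (adjusted p = 0.00331), 1.49 ± 0.34 for COX6C (adjusted p = 0.0105) and 1.97 ± 0.41 for CDKN1A (adjusted p = 0.00524). NDUFS8 stood at 4.72 without combination replicate 3 of 92.1. By list, S phase genes (3 of 29 higher in OMM1, 6 over the list alone, median 0.69, adjusted p = 2.55e-05; 0.0275 with estimated correlation) and tRNA synthetases (median -0.38, adjusted p = 0.019; 0.0414 with estimated correlation) differed. With the preset correlation there were 3 more. They were nuclear OXPHOS subunits (7 higher in OMM1, 9 over the list alone, median 0.54, adjusted p = 2.55e-05, but 0.263 with estimated correlation), G2 and mitosis (1 higher, 5 over the list alone, median 0.61, adjusted p = 0.00386, but 0.0545 with estimated correlation) and p53 targets (2 higher, 4 over the list alone, median 0.16, adjusted p = 0.0449, but 0.0844 with estimated correlation). All calls named here end with library weights, where the count is 2, and it is 25 with only the 4 groups fitted, 152 with thinned counts and 504 with DESeq2. The count was 139 without NTC ASO replicate 4 of 92.1, 465, 499 and 437 without combination replicates 1, 3 and 4 of 92.1, and 122, 143 and 141 without NTC ASO replicates 2, 3 and 4 of OMM1.

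Cell cycle genes were lower with the combination than with the SAMMSON ASO alone in 92.1 (n = 4 and 4). Of 29 genes of G2 and mitosis 3 fell, 5 over the list alone (median -0.82, adjusted p = 6.63e-07; 0.00907 with estimated correlation). Among them are TOP2A, DNA topoisomerase II alpha (-1.13 ± 0.15, 2.18-fold, adjusted p = 3.45e-05), and MKI67 (-2.39 ± 0.39, 5.24-fold, adjusted p = 0.000464). Of 29 S phase genes 2 fell, 7 over the list alone (median -0.60, adjusted p = 2.77e-05; 0.0414 with estimated correlation). GINS1 fell to 1 count from 150 (ratio 138, 24.3 to 5470). Ribosomal proteins rose (14 of 83, 34 over the list alone, 0 and 1 fell, median 0.31, adjusted p = 1.04e-20, but 0.077 with estimated correlation). RPL13A rose by 0.86 ± 0.12 (1.81-fold). FOXO targets (0 of 26, median 0.28, adjusted p = 0.0451, but 0.077 with estimated correlation) and mitochondrially encoded mRNAs (0 of 13, 3 and 1 over the list alone, median 0.13, adjusted p = 0.016, but 0.646 with estimated correlation) shifted up. The largest single changes were MRPL30 (2.19 ± 0.57, 4.58-fold, adjusted p = 0.0327), SUMF1 (2.15 ± 0.54, 4.45-fold, adjusted p = 0.0239) and SLC4A1AP (1.89 ± 0.42, 3.7-fold, adjusted p = 0.00872) upward, and ACBD6, at least 34.5-fold, NFKBIZ, at least 31.4-fold, and GINS1 downward.

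In total 228 of 10936 genes differed between the combination and the SAMMSON ASO in 92.1, 37 higher and 191 lower (64 and 169 with RLE scaling). With only the 2 groups fitted the count was 19 (13 higher, 6 lower) and with library weights 35 (27 and 8). The calls of MKI67, GINS1, ACBD6, NFKBIZ and MRPL30 ended under both, while those of SUMF1 and SLC4A1AP ended with only the 2 groups. DESeq2 called 654. The count was 147 without SAMMSON ASO replicate 3, and 420 and 391 without combination replicates 3 and 4. MRPL30 lost its call without any SAMMSON ASO library or combination replicate 3 (adjusted p up to 0.0938), SUMF1 without SAMMSON ASO replicate 1, 3 or 4 (up to 0.0927; 2.84 without replicate 2), and NFKBIZ without SAMMSON ASO replicate 1, 2 or 4 (up to 0.0591).

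Stress and p53 genes were higher with the combination than with GDC-0349 alone in 92.1 (n = 4 and 4). Of 29 ATF4 targets 9 rose and 0 fell, 13 and 1 over the list alone (median 1.29, adjusted p = 2.86e-12; 7.37e-05 with estimated correlation). They hold DDIT3 (4.20 ± 0.48, 18.4-fold, adjusted p = 2.14e-07), ATF4 (1.84 ± 0.19, 3.57-fold) and ASNS (2.42 ± 0.34, 5.36-fold). Of 28 p53 targets 7 rose and 0 fell, 8 and 0 over the list alone (median 0.79, adjusted p = 8.04e-07; 0.00177 with estimated correlation). They hold GADD45A (3.13 ± 0.39, 8.78-fold, adjusted p = 1.23e-06) and CDKN1A (2.88 ± 0.39, 7.36-fold, adjusted p = 4.66e-06). The p53 list was not called for the combination against NTC ASO (median -0.006, adjusted p = 0.465, CDKN1A at -0.68 ± 0.34), and NTC ASO over DMSO alone gave a median of 0.69. For ATF4 targets NTC ASO over DMSO gave 0.52, and for BBC3 4.25-fold. Of 12 BCL2 family genes 4 rose, 4 and 1 over the list alone (median 0.26, adjusted p = 0.00388; 0.0467 with estimated correlation). PMAIP1 (3.84 ± 0.47, 14.3-fold) and BBC3 (2.54 ± 0.38, 5.79-fold) are among them. Ribosomal proteins rose (38 of 83, 54 over the list alone, 0 and 3 fell, median 0.52, adjusted p = 2e-24; 0.0467 with estimated correlation). The largest single changes were MAP7D2, at least 87.3-fold, LRRC15, at least 63.4-fold, and CCDC168, at least 61.1-fold higher. Lower were CNPY3, at least 59.5-fold, ABCC4, at least 54.1-fold, and ANO10, at least 48.3-fold lower, the last with no call under library weights.

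Of 10 lists called there with the preset correlation, these 4 held with the estimated one. Those that did not include S phase genes (4 of 29 fell, 6 over the list alone, median -0.43, adjusted p = 0.00945, but 0.129 with estimated correlation) and cholesterol synthesis (3 of 23 rose and 1 fell, median 0.52, adjusted p = 0.011, but 0.0842 with estimated correlation). In total 946 of 10936 genes differed, 356 higher and 590 lower. Of the rises, 47 were also rises of the SAMMSON ASO against NTC ASO (2.31 expected). The total was 217 with only the 2 groups fitted (138 higher, 79 lower), 344 with library weights (245 higher, 99 lower), 1521 with DESeq2, 595 without GDC-0349 replicate 1 and 614 without GDC-0349 replicate 3.

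Genes of G2 and mitosis were lower with the combination than with the SAMMSON ASO alone in OMM1 (n = 4 and 4): 2 of 29 fell, 6 over the list alone (median -0.32, adjusted p = 9.58e-05; 0.005 with estimated correlation). TPX2, a spindle assembly factor, fell by 0.81 on the log2 scale (1.75-fold, adjusted p = 0.00945). That call ended without SAMMSON ASO replicate 1 or combination replicate 1 (up to 0.0679). CAPN3 fell (-1.62 ± 0.26, 3.07-fold, adjusted p = 0.00038) and RPL36AL rose (1.20 ± 0.20, 2.3-fold, adjusted p = 0.000769). The other largest changes were MMP11 (1.92 ± 0.47, 3.79-fold, adjusted p = 0.0376), SERTAD4 (1.90 ± 0.38, 3.72-fold, adjusted p = 0.00662), SEC61G (1.64 ± 0.41, 3.13-fold, adjusted p = 0.0458), RN7SL3 (-1.92 ± 0.40, 3.78-fold, adjusted p = 0.00855) and ZBTB40 (-1.61 ± 0.39, 3.05-fold, adjusted p = 0.0374). MMP11 lost its call without SAMMSON ASO replicate 1, 2 or 4 or combination replicate 1, 2 or 4 (up to 0.149). SEC61G lost it without any library but combination replicate 3 (up to 0.144) and ZBTB40 without any but combination replicate 2 (up to 0.128). SERTAD4 lost it without combination replicate 1 (0.0584) and RN7SL3 without SAMMSON ASO replicate 1 (0.0614). RN7SL3 stood at -2.70 without combination replicate 2. With library weights the calls of MMP11, SERTAD4 and ZBTB40 ended, those of MMP11 and ZBTB40 with thinned counts too.

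By list, tRNA synthetases (0 of 20, 4 fell over the list alone, median -0.22, adjusted p = 0.00361; 0.0375 with estimated correlation) and mitochondrial chaperones (1 of 15 fell, 3 over the list alone, median -0.24, adjusted p = 0.0101; 0.046 with estimated correlation) also moved down in OMM1 against the SAMMSON ASO. Autophagy genes moved up (0 of 29, 3 over the list alone, median 0.17, adjusted p = 0.0266; 0.048 with estimated correlation). OXPHOS subunits (2 of 52 rose, median 0.29, adjusted p = 0.00361, but 0.341 with estimated correlation), ribosomal proteins (5 of 83 rose, 23 and 2 over the list alone, median 0.21, adjusted p = 2.1e-07, but 0.266 with estimated correlation) and FOXO targets (0 of 25, 2 over the list alone, median 0.29, adjusted p = 0.0314, but 0.09 with estimated correlation) moved up with the preset correlation. In total 75 of 13200 genes differed, 30 higher and 45 lower. The total was 22, 36 and 41 without SAMMSON ASO replicates 1 to 3, 35 without combination replicate 1, 138 without the low-count filter, 234 with DESeq2 and 129 with the replicate block. The balance turned to 77 higher and 34 lower with only the 2 groups fitted, 52 and 20 with library weights and 72 and 66 without the filter.

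The p53 targets were higher with the combination than with GDC-0349 alone in OMM1 (n = 4 and 4): 13 of 29 rose and 0 fell, 18 and 0 over the list alone (median 0.95, adjusted p = 2.25e-17; 1.46e-06 with estimated correlation). GADD45A rose 14-fold (3.81 ± 0.21, adjusted p = 5.96e-19), TRIAP1 4.47-fold (2.16 ± 0.16) and CDKN1A 3.79-fold (1.92 ± 0.21). FGF18 rose 80-fold (6.32 ± 0.54, adjusted p = 1.95e-12) and PMAIP1 16.5-fold (4.04 ± 0.49). ATF4 targets rose, 12 of 30 with 0 falls, 14 and 1 over the list alone (median 0.63, adjusted p = 4.07e-07; 0.0146 with estimated correlation). ATF4 (1.45 ± 0.17, 2.73-fold) and SESN2 (2.09 ± 0.29, 4.26-fold) are examples. Genes of G2 and mitosis fell, 12 of 29 with 1 rise, 13 and 1 over the list alone (median -0.45, adjusted p = 0.00156; 0.0146 with estimated correlation). TOP2A (-0.63 ± 0.13) and MKI67 (-0.98 ± 0.22) are examples. The other largest changes were H2BC21 (5.0 ± 1.13, 32-fold, adjusted p = 0.00135), SFN (4.82 ± 1.05, 28.3-fold, adjusted p = 0.000907), ZDHHC11B (-4.10 ± 0.70, 17.2-fold, adjusted p = 2.87e-05), AKAP11 (-3.05 ± 0.59, 8.28-fold) and TRIM71 (-2.82 ± 0.52, 7.04-fold). Without GDC-0349 replicate 4 FGF18 stood at 7.23 and H2BC21 at 5.81, and without combination replicate 3 ZDHHC11B stood at -5.13.

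Ribosomal proteins (69 of 83 rose, 73 and 1 over the list alone, median 0.72, adjusted p = 6.99e-35; 0.0146 with estimated correlation), MYC targets (9 of 30 rose and 1 fell, 13 and 1 over the list alone, median 0.42, adjusted p = 0.00156; 0.0146 with estimated correlation) and heat shock genes (5 of 15 rose, 6 and 1 over the list alone, median 0.42, adjusted p = 0.00214; 0.0418 with estimated correlation) were higher too. Lysosome genes (10 of 39 rose, 11 over the list alone, median 0.44, adjusted p = 0.00156, but 0.0861 with estimated correlation), OXPHOS subunits (26 of 52 rose and 1 fell, 30 and 1 over the list alone, median 0.64, adjusted p = 1.51e-09, but 0.0888 with estimated correlation) and mitochondrially encoded mRNAs (7 of 13 rose and 1 fell, 10 and 2 over the list alone, median 0.40, adjusted p = 0.00342, but 0.126 with estimated correlation) rose with the preset correlation. In all 11 lists were called, 6 of them also with estimated correlation. In total 1876 of 13200 genes differed, 1010 higher and 866 lower. Of the rises, 250 were also rises of the SAMMSON ASO against NTC ASO (26.2 expected).

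**Figure D4:**
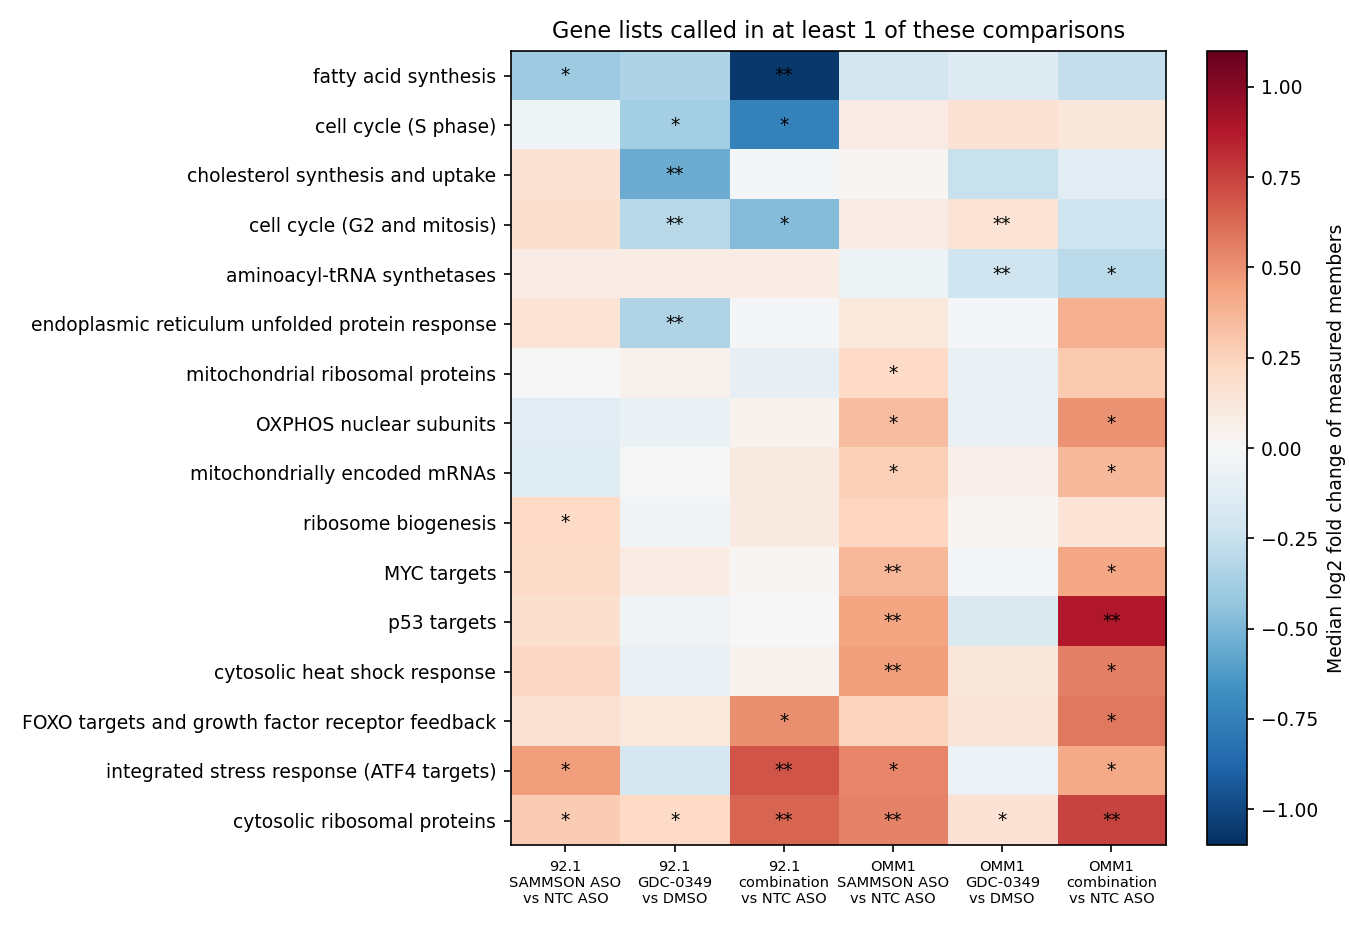
Median log2 fold change of the members of each fixed gene list in the comparisons of SAMMSON ASO and combination with NTC ASO and of GDC-0349 with DMSO, by line. Ribosomal proteins are at 0.28 and 0.55 under the SAMMSON ASO in 92.1 and OMM1, 1 star marks a camera adjusted p under 0.05 and 2 stars mark one that holds with estimated correlation.

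The interaction tested whether the combination departed from the sum of the single effects. If the GDC-0349 and DMSO wells held no ASO, it also takes in any effect of GDC-0349 with an ASO as such. In 92.1, 6 of 10936 genes were called, all lower than the sum: BAIAP2L1 (-5.50 ± 1.00, adjusted p = 0.0253), TOP2A (-1.02 ± 0.21, adjusted p = 0.0471), and ABCC4 and ACBD6 (both adjusted p = 0.0471), whose sizes are not given since the combination had no counts of them. CD36 (-1.19 ± 0.22) and RNU4ATAC (-1.37 ± 0.28) lie outside the rule and were chosen after their values were seen. BAIAP2L1 had counts in combination replicate 1 alone of its group. The count was 0 without DMSO replicate 1, 2 or 3 or GDC-0349 replicate 1, 2 without GDC-0349 replicate 4 or SAMMSON ASO replicate 3, and 41, 38, 50 and 59 without combination replicates 1 to 4. It was 3 with RLE scaling (1 higher, 2 lower), 6 with library weights (3 higher, 3 lower, 2 calls kept), 18 without the low-count filter, 74 with DESeq2, 3 with the replicate block, 2 without the most counted genes and 0 with only the 4 groups fitted. In OMM1 edgeR called 0 of 13200 genes, with 881 at an unadjusted p under 0.05. The OMM1 count was 13 with DESeq2, 3 with library weights, 5 without the low-count filter and 2 each with RLE scaling, the replicate block and without the most counted genes. Fits without 1 library gave 0 to 3.

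By list, genes of G2 and mitosis were lower than the sum in OMM1 (0 of 29 called, 7 over the list alone, median -0.62, adjusted p = 8.42e-08; 0.000297 with estimated correlation). The p53 targets were higher there (0 of 29, 1 over the list alone, median 0.35, adjusted p = 0.00192; 0.0107 with estimated correlation). OXPHOS subunits were higher in OMM1 with the preset correlation (0 of 52, 1 over the list alone, median 0.36, adjusted p = 0.000505, but 0.432 with estimated correlation). In 92.1, 4 lists passed with the preset correlation and 0 with the estimated one. Of these, genes of G2 and mitosis were lower (1 of 29 called, 2 over the list alone, median -0.35, adjusted p = 0.0202, but 0.319 with estimated correlation).

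NTC ASO wells and DMSO wells, as labelled, differed in a few genes (n = 4 and 4 in each line). By the series text both could have held NTC ASO and DMSO, so none of these differences, p53 and ATF4 targets included, is known to come from the NTC ASO. NEAT1, a nuclear long non-coding RNA, was lower with NTC ASO in both: by -1.01 ± 0.11 in 92.1 (adjusted p = 1.46e-07, chosen after its value was seen) and from 4260 ± 777 to 1920 ± 139 CPM in OMM1 (-1.15 ± 0.11, 2.21-fold, adjusted p = 8.06e-10). In 92.1 CDKN1A was higher (2.38 ± 0.37, 5.2-fold, adjusted p = 0.000737) and HUWE1, a ubiquitin ligase, lower (-1.50 ± 0.24, 2.83-fold, adjusted p = 0.0013). BBC3 (2.09 ± 0.39, 4.25-fold, adjusted p = 0.0103) was higher, a call that ended without NTC ASO replicate 2 or 3 or DMSO replicate 1 or 3 (up to 0.0847). SLC25A16 (-1.96 ± 0.39, 3.88-fold, adjusted p = 0.0213) was lower, a call that ended without any library but NTC ASO replicate 2 and DMSO replicate 1 (up to 0.148). The calls of SNHG32 (1.29 ± 0.27, up to 0.354) and PTPN12 (-1.65 ± 0.36, up to 0.323) ended without any library. In OMM1 SMG1 (-0.97 ± 0.18, 1.96-fold, adjusted p = 0.0178), HUWE1 (-0.91 ± 0.19, 1.88-fold, adjusted p = 0.038), SEMA5A (-0.66 ± 0.13, adjusted p = 0.0311) and VRK2 (-1.81 ± 0.37, adjusted p = 0.038) were lower, SEMA5A and VRK2 being chosen after their values were seen. SMG1 lost its call without NTC ASO replicates 2 to 4 or DMSO replicate 1 (up to 0.123), and HUWE1 in OMM1 without any library but DMSO replicate 4 (up to 0.226). Both calls ended with only the 2 groups fitted.

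The totals were 11 of 10936 genes in 92.1 (5 higher, 6 lower, 6 and 4 with RLE scaling) and 5 of 13200 in OMM1. The 92.1 count was 7, 6, 4 and 5 without NTC ASO replicates 1 to 4, 5, 7, 4 and 5 without DMSO replicates 1 to 4, 40 with DESeq2, 72 with only the 2 groups fitted and 82 with library weights. The OMM1 count was 1, 1 and 2 without NTC ASO replicates 2 to 4, 1, 2 and 17 without DMSO replicates 1, 2 and 4, 29 with DESeq2 and 1 with only the 2 groups fitted. By list, 7 were called in 92.1 and 4 in OMM1. The p53 targets were higher with NTC ASO in 92.1 (2 of 28 called, median 0.69, adjusted p = 3.89e-10; 0.000194 with estimated correlation) and in OMM1 (0 of 29, 2 over the list alone, median 0.18, adjusted p = 0.00574; 0.0321 with estimated correlation). ATF4 targets were higher in 92.1 (0 of 29, 1 over the list alone, median 0.52, adjusted p = 7.66e-07; 0.0035 with estimated correlation) and in OMM1 (0 of 30, 2 over the list alone, median 0.18, adjusted p = 0.00678, but 0.208 with estimated correlation). The others held only with the preset correlation. In 92.1 fatty acid synthesis (median 0.21, adjusted p = 0.0299), OXPHOS subunits (0.26, 6.2e-07), mitochondrially encoded mRNAs (0.13, 0.00394) and the BCL2 family (0.15, 0.0332) were higher and S phase genes (-0.26, 0.0385) lower. In OMM1 ribosomal proteins (0.094, 0.0022) were higher and YAP targets (-0.32, 0.0146) lower.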

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

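The tests on the 92.1 combination calls, read-through and the most counted genes were chosen after results were seen, the matched ribosomal lists and label splits before. In 6 of 100 screens of 4 replicates, 1 library lay far from the other 3; chance alone gives about 1 in 20. GDC-0349 replicate 3 of 92.1 held 3021013 counts (others 763610 to 1036265). DMSO replicate 1 of OMM1 had 4.329 percent of its counts in long non-coding RNAs (others 3.388 to 3.508). Combination replicate 4 of OMM1 had 4.323 percent (3.969 to 3.99), and 15.48 percent in the 10 most counted genes (16.247 to 16.296). SAMMSON stood at 43 CPM in DMSO replicate 1 of 92.1 (others 0.56 to 6.82) and at 12.5 CPM in combination replicate 4 of 92.1 (0 to 1.25). Outside these screens, SAMMSON ASO replicate 1 of OMM1 lay at -119.72 on principal component 2 (others of its group -3.4 to 1.45) and combination replicate 2 of 92.1 at 127.22 (-83.49 to -35.21).

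The lines differed, by test of the difference, in the response to GDC-0349 of 4 lists: tRNA synthetases (median -0.24), G2 and mitosis (0.51), S phase (0.44) and cholesterol synthesis (0.34). They differed in the response to the combination in 229 genes, in tRNA synthetases (-0.38) and in S phase genes (0.69).

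The 843 calls of the 92.1 combination against NTC ASO come from the libraries of widest spread. A spread wider than the shared estimate allows could account for many: the fit of the 2 groups alone kept 29.5 percent of the calls, library weights 25.6 percent. Loss of rare transcripts from libraries of low complexity could account for falls seen in 92.1 alone. Of the called falls tested in OMM1, 77.7 percent had the same sign there, against at most 55.5 percent in 1000 random sets (median 48.6). Of the rises 93 percent did, against at most 62.1 percent, so low complexity does not account for all directions. The falls had a median of -2.37 in 92.1 and -0.50 in OMM1, and 70 of 488 had no counts in the combination, so low complexity may add to their size and number.

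Ribosomal protein mRNAs are abundant and short, and such transcripts may gain share together under the SAMMSON ASO. Against 10000 random lists matched for level and length (median 0.21), the OMM1 median of 0.55 exceeded the highest, 0.4. The 92.1 median of 0.28 lay above the matched 95th percentile of 0.27 (median 0.16) but below the highest, 0.35, and cannot tell. Without the 10 most counted genes of each line, some ribosomal, the medians were 0.27 in 92.1 and 0.55 in OMM1. TMM already limits such genes, so they are not excluded as a cause. In OMM1 an effect of the SAMMSON ASO stays open as a hypothesis, with off-target effects untested. The list also had medians of 0.22 in 92.1 and 0.16 in OMM1 under GDC-0349 alone, so a shared response is open too.

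Some genes rose from under 2 CPM, which read-through from an expressed gene within 10000 bases upstream on the same strand could produce. The exact Fisher test over 12 tests gave an adjusted p of 0.74 for the SAMMSON ASO against NTC ASO, 0.458 for the combination against NTC ASO and 0.598 against GDC-0349 in 92.1. In OMM1 it gave 0.557, 0.13 and 0.0437. In the last, 22 of 53 rises had such a neighbour against 141 of 636 other genes (odds ratio 2.49, 1.33 to 4.6). A neighbour on the opposite strand, not needed for read-through, gave 1.55 (0.778 to 2.95), which overlaps. Under the SAMMSON ASO in OMM1 it gave 2.85 (0.958 to 8.17) against 1.64 (0.495 to 4.8). Read-through stays open in all 6. No biological explanation was tested.

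Group labels were split to ask whether chance can be excluded. For comparisons with the 92.1 combination the splits cannot tell, since mixed groups share its wide spread. The real count of genes was the highest of 35 splits (1 of 35) for the SAMMSON ASO in 92.1 (88, next 0) and OMM1 (515, next 3), the combination against NTC ASO (843, next 5; 1802, next 1), against SAMMSON ASO (228, next 20; 75, next 3) and against GDC-0349 (946, next 23; 1876, next 1). It was so too for NTC ASO against DMSO in 92.1 (11, next 0) and OMM1 against 92.1 under DMSO (2298, next 112). Chance cannot be excluded for GDC-0349 in OMM1 (5, 3 of 35, highest 56) and NTC ASO against DMSO in OMM1 (5, 5 of 35, highest 42). A real count of 0 is matched by every split and so tests nothing. This holds for GDC-0349 in 92.1 (35 of 35, highest 8), the OMM1 interaction (100 of 100, highest 159) and the line differences in SAMMSON ASO (60 of 60, highest 24) and GDC-0349 (60 of 60, highest 8). The 92.1 interaction (6, 3 of 100, highest 63) and the line difference in the combination (229, 2 of 60, highest 417) were rarely matched. Why some splits had several times the real count, as in 56, 42 and 63, was not tested. For lists, the real counts were the highest for the combination in 92.1 (6, 1 of 35, next 5) and the SAMMSON ASO in OMM1 (8, 1 of 35, next 7). They were matched for the SAMMSON ASO in 92.1 (4, 3 of 35, highest 5), GDC-0349 in 92.1 (5, 7 of 35, highest 8) and OMM1 (3, 7 of 35, highest 6) and the combination in OMM1 (9, 2 of 35, highest 9). Lists of the interactions and of the line differences were not tested by splits.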

How the results depend on the processing

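Apart from spread in the 92.1 combination, why counts of called genes moved was not tested. Counts moved over 1.5 times follow by setting. RLE scaling gave 3 for the 92.1 interaction, and in OMM1 2 for NTC ASO against DMSO and 2 for the interaction. Without the low-count filter, which tests more genes, GDC-0349 had 5 in 92.1 and 20 in OMM1, NTC ASO against DMSO 17 and 18, the interaction 18 and 5, the OMM1 combination against SAMMSON ASO 138, and the line differences in SAMMSON ASO and GDC-0349 5 and 2. DESeq2 gave in 92.1 240 for SAMMSON ASO, 21 for GDC-0349, 1380, 654 and 1521 for the combination against NTC ASO, SAMMSON ASO and GDC-0349, 40 for NTC ASO against DMSO and 74 for the interaction. In OMM1 it gave 22 for GDC-0349, 234 for the combination against SAMMSON ASO, 29 for NTC ASO against DMSO and 13 for the interaction, and for the line differences 12, 1 and 504. With only the groups compared, 92.1 had 238 for SAMMSON ASO, 256, 19 and 217 for the combination, 72 for NTC ASO against DMSO and 0 for the interaction. OMM1 had 1 for GDC-0349 and 1 for NTC ASO against DMSO, and the line difference in the combination 25.

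Of settings chosen after seeing the data, library weights gave in 92.1 345 for SAMMSON ASO, 60 for GDC-0349, 223, 35 and 344 for the combination and 82 for NTC ASO against DMSO. They gave in OMM1 22 for GDC-0349, 10 for NTC ASO against DMSO and 3 for the interaction, 4 and 2 for the line differences in GDC-0349 and the combination, and 3817 for OMM1 against 92.1. Thinning to the smallest total gave in OMM1 3 for GDC-0349 and 3 for NTC ASO against DMSO, and 152 for the line difference in the combination. Without the most counted genes, 92.1 had 6 for NTC ASO against DMSO and 2 for the interaction, OMM1 2 for GDC-0349, 2 for NTC ASO against DMSO and 2 for the interaction. Without the combination libraries, 92.1 had 300 for SAMMSON ASO, 3 for GDC-0349 and 30 for NTC ASO against DMSO, OMM1 2 for GDC-0349 and 8 for NTC ASO against DMSO.

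Same-numbered replicates correlated weakly, averaging 0.00475 in 92.1 and 0.00858 in OMM1 (other numbers -0.00142 and -0.00281). In either line 0 of 40 pairs passed 0.1. Of 20 libraries, 6 and 10 correlated best with their own number, so OMM1 pairing stays open. The replicate block gave 1 for GDC-0349 and 3 for the interaction in 92.1. In OMM1 it gave 9 for GDC-0349, 129 for the combination against SAMMSON ASO, 3 for NTC ASO against DMSO and 2 for the interaction, and 1417 for OMM1 against 92.1.

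Leaving out 1 library gave, in 92.1, 41 to 78 for SAMMSON ASO, 0 to 2 for GDC-0349, 554 to 1076, 147 to 420 and 595 to 1114 for the combination, 4 to 7 for NTC ASO against DMSO and 0 to 59 for the interaction. In OMM1 the ranges were 312 to 456, 1 to 34, 1359 to 1635, 22 to 81, 1384 to 1671, 1 to 17 and 0 to 3. For the line differences they were 0 to 0, 0 to 1 and 122 to 499, and for OMM1 against 92.1 1824 to 1974. With an estimated correlation 45 of 109 list calls held; no list call turned its direction. No called gene named by the rule reversed: with DESeq2 692 of 696 kept their call, with only the groups compared 544 of 690, with library weights 543 of 709 and with thinned counts 595 of 681. The uncalled change of SAMMSON in 92.1 with the combination against GDC-0349 (-0.015) was 0.048 with RLE scaling, 0.047 with DESeq2, 0.012 without the most counted genes and -0.405 to 0.369 without 1 library, above 0 without GDC-0349 replicates 2 to 4 (0.23, 0.101, 0.054) or combination replicates 1 to 3 (0.369, 0.263, 0.296).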

Other observations

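The test of snoRNA host genes was chosen after results were seen. Under DMSO, 2298 of 14048 genes were called between OMM1 and 92.1 (n = 4 and 4). KIT, a receptor tyrosine kinase of melanocytes, was 91.7-fold higher in OMM1 (6.52 ± 0.49, adjusted p = 7.78e-17), and SLC45A2, a melanosomal transporter, 14.4-fold (3.85 ± 0.31). FGF9 was at least 518-fold and IRX2 at least 112-fold lower. Ribosomal protein genes were lower in OMM1 (6 of 83 higher and 54 lower, 8 and 59 over the list alone, median -0.68, adjusted p = 3.29e-19, but 0.054 with estimated correlation), with RPS20 at -1.96 ± 0.14 (3.9-fold). The p53 targets (11 higher, 0 lower, 12 and 0 over the list alone, median 0.94, adjusted p = 6.7e-05, and 0.00115 with estimated correlation) and glycolysis genes (10 higher, 1 lower, median 0.59, adjusted p = 6.7e-05, and 0.000707 with estimated correlation) were higher, such as ALDOA, an aldolase (2.28 ± 0.17, 4.87-fold).

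Markers of other cell types were low: summed group means ran from 3.03 to 32.6 CPM for fibroblasts, 1.74 to 59.7 for leukocytes, 5.59 to 26.8 for endothelium and 15.9 to 72.7 for epithelium. Some went up with the combination: leukocyte markers in 92.1 from 5.66 ± 5.09 CPM with NTC ASO and 1.74 ± 2.68 with GDC-0349 to 36.4 ± 14.4, and fibroblast markers in OMM1 from 14.1 ± 6.25 with NTC ASO to 32.6 ± 9.34. CD68 in 92.1 had 116 counts against 2 with GDC-0349 (ratio 66.9, 18.1 to 559). The mitochondrial rRNAs MT-RNR1 and MT-RNR2 summed to 37300 to 41100 CPM in 92.1 and 43200 to 54300 in OMM1, and MT-RNR1 fell with the combination (-0.51 ± 0.09 in 92.1, adjusted p = 0.00021, and -0.45 ± 0.10 in OMM1, adjusted p = 0.000976).

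A hypothesis from SNHG1 and SNHG25 is that non-coding snoRNA hosts (SNHG genes, GAS5, ZFAS1, EPB41L4A-AS1, DANCR) may rise as a class under the SAMMSON ASO. Tested without the named genes, 3 of 20 hosts rose in 92.1 (median 0.37, adjusted p = 4.59e-06, and 0.00958 with estimated correlation) and 7 of 22 in OMM1 (median 0.71, adjusted p = 8.73e-07, and 0.0216 with estimated correlation), by camera. The hosts also shifted up under GDC-0349 in 92.1 (0 of 20 called, adjusted p = 0.000523) but not in OMM1 (adjusted p = 0.724). Neither ASO specificity nor an excess over matched genes is shown.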
